A study of Mus musculus with 16 samples.

How the data were processed

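Cultured mouse KP lung adenocarcinoma cells, control or with a knockout of Sphk1, were measured by RNA-seq with and without 10% FCS, in 16 libraries. Per the labels' protocols, RNA was isolated with the RNeasy Mini kit, poly(A) RNA was selected, and libraries were made with the NEBNext Ultra II Directional kit. The authors deposited raw read counts per gene, 1 file per library without a header, with 55421 gene rows and 4 tally rows for unmapped, multimapping, unassigned and ambiguous reads. Per the submitters' processing notes, STAR 2.6.1a was used, and the build named there is GRCh38. That is a human build, while the gene identifiers in the files are mouse Ensembl identifiers. Of these, 98.65% equal those of GENCODE M21 (mouse, GRCm38) with their version, 567 more match without the version and 181 match none. Symbols and coordinates were therefore taken from GENCODE M21. The annotation release used for counting, the strand setting and any trimming are not given in the sources used here.

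The tally rows were kept out of library sizes and tests. Gene rows held 80.3% to 81.9% of the tallied reads, multimapping reads 10.2% to 11.8%, unmapped reads 1.63% to 2.02%, reads in no gene 4.00% to 5.79% and ambiguous reads 1.36% to 1.47%. Totals of gene counts were 21621606 to 27151199 per library. Mitochondrial genes took 1.23% to 1.76% of gene counts, and the top 10 genes of a library 3.77% to 4.50%. No pair of libraries within a group was a duplicate: the chi-square of their counts per degree of freedom was 1.67 to 7.93.

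Groups were taken from the sample titles. Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 13749, and libraries were scaled with TMM factors. A quasi-likelihood model with 1 coefficient per group was fitted to the 16 libraries, without a term for the replicate number. The 5 contrasts tested were SPHK1 loss without FCS, SPHK1 loss with FCS, FCS in control cells, FCS in dSPHK1 cells, and the interaction. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called with an adjusted p under 0.05. The common biological coefficient of variation was 0.038. Standard errors of log2 fold changes were derived from the fold change and the F statistic of the test. CPM are counts scaled to a common library size with TMM factors, given as mean ± SD over the 4 libraries of a group. Where a group had 0 counts for a gene, a fold is given as at least the ratio to a floor of 3 counts over the group, and with 1 to 3 counts as the ratio with an exact 95% interval of the counts.

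Gene lists, 30 in number, were tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes where at least 3 members were tested, adjusted over the lists of a comparison, and again with the correlation estimated from the data. The per-gene p-values were also adjusted over each list alone. The groups, tests, gene lists, alternatives and the rule for naming genes were set before the data were examined. The rule took the 6 rising and 6 falling genes with the largest fold changes in each pairwise comparison (5 and 5 for the interaction) among called genes with a mean of at least 5 CPM in the higher group and, in the pairwise comparisons, no overlap between the groups. It passed over predicted genes without a proper name and mitochondrial genes. It took up to 3 called members of each called list and 1 of the other direction, up to 4 of the attractant, sphingolipid and S1P receptor lists, and Sphk1, Sphk2, Kras, Trp53, Ccl2 and Csf1 in any case. Markers of macrophages, fibroblasts, endothelium and lymphocytes were among the lists.

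The steps were tested on simulated counts with 1 mean per gene pooled over all libraries, the sizes of the real libraries and 200 changed genes. Of genes changed 1.5-fold, 94% were recovered for SPHK1 loss without FCS, 89% with FCS, 94% for FCS in control cells, 90% for FCS in dSPHK1 cells and 79% for the interaction. Of genes changed 2-fold, 99%, 98%, 97%, 98% and 96% were recovered in the same order. Of 13238 to 13259 unchanged genes 7 to 23 were called. In each comparison a simulated list of 20 genes changed 1.5-fold was called, and none of 19 unchanged lists was. The simulated genes were drawn independently of each other. How often an unchanged list of correlated genes would be called was therefore not tested. Few genes changed in the simulation, while 73.4% of those tested were called for SPHK1 loss without FCS. The scaling and the false calls under so wide a difference were not tested either.

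Genome windows were runs of 50 tested genes in the order of GENCODE M21, compared with 1000 shuffles of the gene order. The alternatives were DESeq2 size factors, upper-quartile factors or library totals, no filter or a filter of 1 CPM in 4 libraries, robust estimation, DESeq2 1.42.0 and limma-voom, a fold change of at least 2, the compared samples alone, a term for the replicate number, each library left out in turn, and, added after the data were seen, control replicate 3 and FCS-treated control replicate 4 both left out, which lay apart from their groups on component 3. Figures were drawn with matplotlib 3.10.9.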

Results

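Poly(A) RNA was sequenced from cultured mouse lung adenocarcinoma cells, named KP by the submitters, which the submitters describe as driven by an activated Kras oncogene and deficient in p53. In some of these cells Sphk1 had been knocked out. Sphk1 encodes sphingosine kinase 1, an enzyme that makes the signalling lipid sphingosine 1-phosphate (S1P). RNA was taken before and after treatment with 10% fetal calf serum (FCS), a source of growth factors and lipids. The duration of the treatment is not given in the sources used here. The 16 libraries fall into 4 groups of 4: control cells without FCS, control cells with FCS, knockout cells without FCS (dSPHK1) and knockout cells with FCS. The series is concerned with the attraction of tumour-promoting macrophages by tumour cells that have lost SPHK1. Gene counts per library ranged from 21621606 to 27151199. The numbers of genes with a count were higher in dSPHK1 libraries (20948 ± 221 without FCS, SD, n = 4) than in control libraries (19659 ± 223). Principal component 1 held 80.7% of the variance and separated control from dSPHK1 libraries, and component 2 held 6.9% and separated the libraries by FCS. The sources do not say whether the 4 libraries of a group came from separate cultures, so the p-values below measure only the spread between these libraries, which may be technical.

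**Figure D1:**
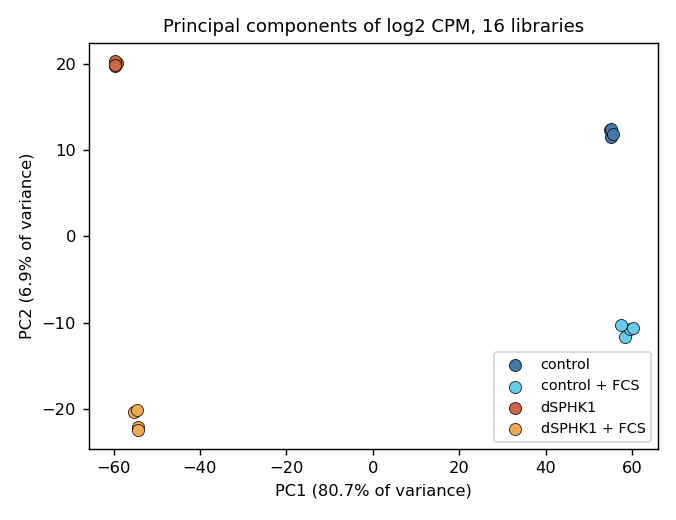
Principal components 1 and 2 of log2 CPM over the 13749 genes tested, 1 point per library, with the percent of variance on each axis. Component 1 (80.7%) parts the 8 control from the 8 dSPHK1 libraries, and component 2 (6.9%) parts libraries with and without FCS.

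Sphk1 RNA was lower in all 8 dSPHK1 libraries than in all 8 control libraries, and it was still present. Sphk1 (ENSMUSG00000061878.15) lies on chromosome 11 of GRCm38, positions 116530925 to 116536674, on the + strand. Its level was 23.2 ± 1.32 CPM (counts scaled to a common library size; SD, n = 4; 22.2 to 25.1) in control cells and 22.3 ± 0.606 CPM (21.8 to 23.1) in control cells with FCS. In dSPHK1 cells it was 11.4 ± 0.652 CPM (10.6 to 12.2), and with FCS 10.98 ± 0.342 CPM (10.6 to 11.4). The log2 fold change was −1.02 ± 0.0558 (SE) without FCS and −1.02 ± 0.0571 with FCS, a 2.03-fold lower level in both settings (adjusted p = 4.3e-15 and 7.5e-15, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). FCS gave no call for Sphk1 in either genotype (log2 fold change −0.06 in both, adjusted p = 0.41 and 0.47). The counts sum over the whole gene, so they do not show where in the gene the edit lies or whether the remaining RNA can be translated. The same holds for Trp53, the p53 gene, whose RNA was present in every library, with group means from 8.75 to 10.7 CPM.

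The comparisons of dSPHK1 with control cells are named SPHK1 loss. The groups do not separate this loss from a difference between the lines or clones that were grown. The comparison without FCS asks how the transcriptomes of the dSPHK1 and control cells differ. The dSPHK1 cells had lower RNA for signals that attract or sustain macrophages, for epithelial markers as a list, for targets of the YAP/TAZ and SRF transcription programmes, and for cholesterol synthesis. Of 15 monocyte and macrophage attractants tested, 12 were lower in dSPHK1 cells and 1 was higher. Csf1, the growth factor that macrophages need to survive, was 246 ± 9.40 CPM (SD, n = 4) in control and 73.5 ± 1.71 CPM in dSPHK1 cells, 3.34-fold lower (log2 −1.74 ± 0.035, SE). The chemokine Ccl9 was 64.1 ± 4.58 CPM in control and 7.12 ± 0.712 CPM in dSPHK1 cells. The keratin Krt7 was 366 ± 8.60 CPM in control and 2.55 ± 0.356 CPM in dSPHK1 cells, 144-fold lower.

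Some genes were at or near 0 in 1 genotype. Map2, a neuronal microtubule protein, had 0 counts over the 4 control libraries and 62.9 ± 2.19 CPM in dSPHK1 cells, at least 2014-fold higher with a floor of 3 counts over the group. Arhgap15, a regulator of the GTPase Rac, was at least 666-fold higher, the secreted protease Adamts9 at least 292-fold and Tmem136 at least 216-fold. Emb, an adhesion protein of the cell surface, had 2 counts over the control libraries against 106 ± 1.66 CPM in dSPHK1 cells, a ratio of 5115 (95% counting interval 1416 to 42238). In the other direction the zinc finger gene Zfp518b had 0 counts over the dSPHK1 libraries and was at least 1299-fold lower. Pogk was lower by a ratio of 1273 (435 to 6177), the surface protein Cdcp1 by 1112 (307 to 9186) and the transcription factor gene Foxd1 by 1341 (240 to 52999). These floors and intervals cover counting error only.

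Most of the gene lists called without FCS had lower RNA in dSPHK1 cells. Of 21 YAP/TAZ targets, which respond to cell shape and tension, 17 were lower and 2 higher (camera adjusted p = 4.5e-13), among them Igfbp3 (log2 −2.82), which fell from 335 to 47.5 CPM, and Nt5e, the surface enzyme CD73 (−4.59). Gadd45a was higher (0.61). Of 19 SRF targets of the actin cytoskeleton, 17 were lower and none higher (adjusted p = 2.8e-07), including smooth muscle actin Acta2 (−2.19) and Tagln (−2.52). Of 23 cholesterol synthesis genes, 22 were lower (adjusted p = 3.0e-11), including Hsd17b7 (−1.43) and Fdps (−1.40), and Insig1, which restrains the same pathway, was higher (0.21). Of 11 epithelial markers, 8 were lower (adjusted p = 1.7e-06), including Krt18 (−1.37) and Krt8 (−1.03), and 3 were higher, with Grhl2 at 3.24. Of 20 genes of the ATF4 amino acid and stress response, 18 were lower (adjusted p = 1.2e-06), including the folate enzyme Mthfd2 (−1.38) and asparagine synthetase Asns (−1.10), while Ddit3 was higher (0.63). Of 15 NF-kB targets, 12 were lower (adjusted p = 0.0013), including Tnfaip3 (−2.41) and Birc3, lower by a ratio of 78.7 (26.6 to 384), and Vcam1 was higher (1.53). The attractants gave adjusted p = 8.1e-05. The genes of growth factor withdrawal were the one list called higher, with 12 of 15 higher (adjusted p = 0.00010), including Txnip, which limits glucose uptake (2.48), and with Erbb3 lower (−0.97). The calls named so far held with an estimated correlation. Calls of lower RNA that did not hold were those of RAS-ERK feedback targets (15 of 21 lower, adjusted p = 2.0e-06 and 0.106 with an estimated correlation), ribosome biogenesis (19 of 20 lower, 1.7e-06 and 0.0754 with an estimated correlation), mitosis (20 of 25 lower, 0.0029 and 0.199 with an estimated correlation), immediate early genes (18 of 27 lower, 0.0099 and 0.338 with an estimated correlation) and fatty acid synthesis (7 of 13 lower, 0.025 and 0.453 with an estimated correlation). Members named by rule in these lists were the ERK phosphatase Dusp5 (−2.69), its relative Dusp4 (2.55), the stearoyl desaturase Scd1 (−1.90), the ephrin receptor gene Epha4 (−2.06), Nop56 (−0.94) and cyclin A2, Ccna2 (−0.79). The counts adjusted over the list alone were the same for the lists above, except that 4 and not 3 RAS-ERK targets were higher.

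Within sphingolipid metabolism, 16 of 34 genes were higher and 11 lower, with the same counts adjusted over the list alone and no shift of the list (camera adjusted p = 0.907). Its median log2 fold change was 0.09 and its mean 0.05, while the test pointed down. The sphingomyelin synthase Sgms2 (−1.60) and the lipid phosphatase Plpp3 (−1.29) were lower, and Sphk2, the second sphingosine kinase, was 38.9 ± 2.21 CPM in control and 42.1 ± 1.69 CPM in dSPHK1 cells (log2 0.12, adjusted p = 0.024). S1pr2, the one S1P receptor with enough counts to test, was lower (−0.60). Kras (−0.05, adjusted p = 0.22) and Trp53 (0.04, adjusted p = 0.72) were not called. The remaining lists were not called (adjusted p from 0.0510 to 0.952): DNA replication, neutrophil attractants, interferon response, antigen presentation, mesenchymal markers, lung lineage, extracellular matrix, hypoxia, unfolded protein response, p53 targets, NRF2 targets, and macrophage, fibroblast and endothelial markers. The median, mean and test differed in sign for mesenchymal markers (median −0.26, mean 0.35, test down), antigen presentation (−0.10, 0.16, down), extracellular matrix (−0.16, 0.58, up) and hypoxia (−0.04, 0.13, up).

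In all, 4998 genes were higher and 5089 lower in dSPHK1 cells of 13749 tested, and 1275 of the former and 758 of the latter differed by at least 2-fold. With library totals in place of TMM factors the higher share of calls was 60.3% against 49.5%. Ccl2, the main monocyte chemokine, was 4.21 ± 0.376 CPM in control and 3.41 ± 0.321 CPM in dSPHK1 cells (log2 −0.31 ± 0.131, adjusted p = 0.036), a call lost with library totals (adjusted p = 0.157) and with limma-voom (0.0648), and without control replicate 1 (0.0603), 2 (0.0874) or 4 (0.0789) or dSPHK1 replicate 1 (0.0910), 2 (0.0768) or 3 (0.0553). The Sphk2 call was lost with no filter on low counts (adjusted p = 0.130) and without control replicate 1 (0.106) or 4 (0.0762) or dSPHK1 replicate 2 (0.0615) or 3 (0.0825).

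**Figure D2:**
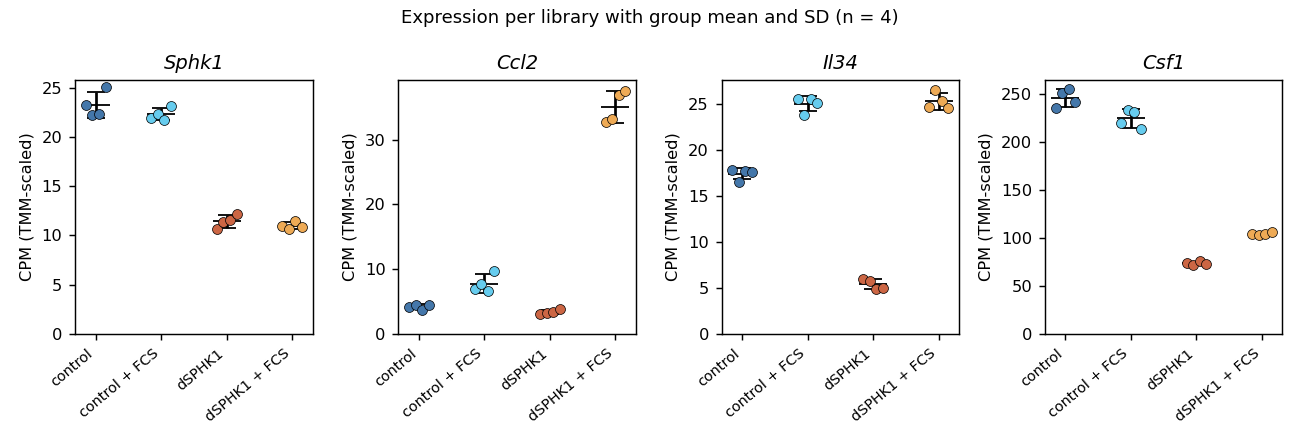
CPM with TMM factors (y axis, linear from 0) of Sphk1, Ccl2, Il34 and Csf1, 1 point per library with the mean and SD of each group of 4. Ccl2 stands at 35.1 CPM in dSPHK1 cells with FCS against 3.41 to 7.77 CPM in the other groups, and Sphk1 is lower in both dSPHK1 groups.

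The differences between the genotypes were uneven across chromosomes. Genes on chromosome 3 were mostly lower in dSPHK1 cells, with 441 of 721 called lower, 128 higher and a median log2 fold change of −0.36. On chromosome 8, 485 of 765 genes were higher, 127 were lower and the median was 0.29, and on chromosome 5 the median was 0.21. The median was −0.26 on chromosome 14 and −0.20 on chromosome 15. With FCS the medians were −0.37 on chromosome 3 and 0.29 on chromosome 8. In windows of 50 neighbouring genes the highest median was 0.94, for genes on chromosome 6 between 124663027 and 128376146 (GRCm38), and the lowest was −0.65, on chromosome 3 between 138526179 and 159938664. The window that holds Sphk1, on chromosome 11 between 116021912 and 119040969, had a median of 0.25, against the −1.02 of Sphk1 itself, and the window that holds Kras, on chromosome 6 between 136872435 and 149583656, had a median of 0.32, against −0.05 for Kras. For the response to FCS in control cells the chromosome medians stayed between −0.02 and 0.02.

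**Figure D3:**
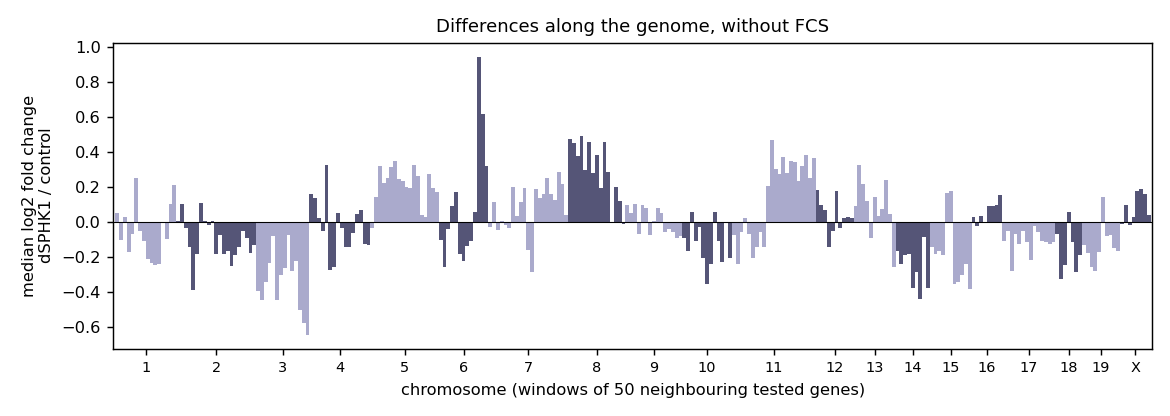
Median log2 fold change of dSPHK1 against control cells without FCS in each of 272 windows of about 50 neighbouring genes, in genome order (x axis, chromosomes 1 to X). Windows of chromosome 3 lie mostly below 0 and those of chromosome 8 mostly above 0, and the highest window, on chromosome 6, is at 0.94.

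The comparison of the genotypes with FCS asks whether the same differences stand in stimulated cells. Most did, while Ccl2, slightly lower in dSPHK1 cells without FCS, was higher with it. Ccl2 was 7.77 ± 1.43 CPM (SD, n = 4) in control and 35.1 ± 2.48 CPM in dSPHK1 cells with FCS, 4.53-fold higher (log2 2.18 ± 0.082, SE; adjusted p = 1.3e-18, edgeR quasi-likelihood test), and the related monocyte chemokine Ccl7 was higher too (log2 3.06 ± 0.319). Csf1 was 225 ± 9.68 CPM in control and 104 ± 1.37 CPM in dSPHK1 cells (log2 −1.11 ± 0.0341), and Ccl9 was 119 ± 10.4 and 12.2 ± 1.499 CPM (−3.29). Of the 15 attractants 5 were higher and 6 lower, with the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.416).

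With FCS, 5004 genes were higher and 5059 lower in dSPHK1 cells, 1311 and 688 of them by at least 2-fold. With library totals 5800 were higher and 4216 lower. Of these calls 4191 were higher and 4274 lower in both comparisons of the genotypes, where independent lists would share 1819 and 1872.5, and 177 were called in opposite directions. The log2 fold changes of the comparisons correlated with Pearson's r = 0.950 and Spearman's rho = 0.888 across genes, which are not independent replicates. Arhgap15 was at least 636-fold higher, the pacemaker channel gene Hcn1 at least 348-fold, the glycogen phosphatase subunit Ppp1r3b at least 388-fold and Bcl7a at least 311-fold. Pogk was at least 1249-fold lower, Zfp518b at least 1245-fold, Foxd1 at least 461-fold, Slc35g2 at least 235-fold and the p53 target Phlda3 at least 170-fold. The receptor phosphatase Ptprf was lower too (log2 −10.29 ± 0.134).

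The YAP/TAZ targets (17 of 21 lower, camera adjusted p = 8.6e-10), the epithelial markers (8 of 11 lower, 3.9e-06) and the ATF4 response (16 of 20 lower, 2.2e-05) were lower in dSPHK1 cells with FCS too, and these calls held with an estimated correlation. Examples are Igfbp3 (log2 −3.20), Krt7 (−6.85), Krt18 (−1.16) and the proline synthesis enzyme Aldh18a1 (−1.21). The SRF targets (17 of 19 lower, 3.3e-05, adjusted p = 0.0603 with an estimated correlation), cholesterol synthesis (21 of 23 lower, 1.3e-07, adjusted p = 0.0566 with an estimated correlation) and ribosome biogenesis (19 of 20 lower, 1.3e-07, adjusted p = 0.0746 with an estimated correlation) were called with the preset correlation only. The same holds for mitosis (21 of 25 lower, 8.8e-05, adjusted p = 0.153 with an estimated correlation), fatty acid synthesis (8 of 13 lower, 0.014, adjusted p = 0.555 with an estimated correlation) and growth factor withdrawal (11 of 15 higher, 0.0058, adjusted p = 0.161 with an estimated correlation). Members were Dhcr24 (−1.40), Cnn2 (−1.12), Nop56 (−0.93), Ccna2 (−0.92), Scd1 (−1.80) and Txnip (1.60), with Insig1 higher (0.79). Adjusted over the list alone these counts were the same.

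Of the sphingolipid genes 14 were higher and 11 lower with FCS, with the same counts adjusted over the list alone (list adjusted p = 0.886). The sphingomyelinase Smpd3 (log2 1.28) and the ceramide kinase Cerk (0.91) were higher, and Sgms2 (−1.02) and S1pr2 (−0.25) lower. Sphk2 (0.21), Kras (0.09, adjusted p = 0.012) and Trp53 (0.28, adjusted p = 0.0079) were called higher by small amounts. The lists of immediate early genes, RAS-ERK targets and NF-kB targets were not called here (adjusted p = 0.957, 0.493 and 0.957), nor were the remaining lists (0.0930 to 0.957). The median, mean and test differed in sign for mesenchymal markers (−0.40, 0.35, down), extracellular matrix (−0.09, 0.64, up), macrophage markers (−0.04, 0.20, up) and antigen presentation (0.08, 0.12, down).

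The comparison of control cells with and without FCS gives the response to serum in cells that keep SPHK1. FCS raised Serpinb2, an inhibitor of plasminogen activators, from 0.932 ± 0.217 to 9.43 ± 0.979 CPM (SD, n = 4; log2 3.33 ± 0.14, SE; adjusted p = 3.6e-15, edgeR quasi-likelihood test), and the collagenase gene Mmp13 3.55-fold. It lowered genes of lipid synthesis: Insig1 fell from 270 ± 5.73 to 127 ± 3.26 CPM (log2 −1.08 ± 0.0292) and Scd1 from 312 ± 8.15 to 191 ± 7.65 CPM (−0.71 ± 0.0318). In all, 2088 genes rose and 2075 fell, 99 and 48 of them by at least 2-fold.

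Other large increases were in the phosphatase Ptpn22 (log2 2.09), Ngef (1.93) and Gcnt1 (1.73). Prl2c2 (3.27) and Prl2c3 (2.94), prolactin family genes, are near-identical copies, so their separate values are uncertain. Large decreases were in Dhrs3 (−1.25), Lpin1 (−1.04), Tenm4 (−1.03), Sesn3 (−0.93) and Fgf1 (−0.90). Of the cholesterol synthesis genes 21 of 23 fell and none rose (camera adjusted p = 1.6e-44), including Lss (−0.68) and Fdps (−0.62), and of the fatty acid synthesis genes 11 of 13 fell (2.2e-23), including Scd2 (−0.76). Ribosome biogenesis genes rose in 15 of 20 cases (1.4e-09; 16 adjusted over the list alone), such as Rrp9 (0.37) and Nop2 (0.30), and unfolded protein response genes in 12 of 16 (4.9e-10), such as Creld2 (0.52) and the chaperone Hspa5 (0.37). NF-kB targets rose in 8 of 15 cases and fell in 1 (1.0e-05; 8 and 2 adjusted over the list alone), with Vcam1 at 0.62, Traf1 at 0.48 and Nfkb2 at 0.42. Neutrophil attractants were called up with 4 of 9 higher and 1 lower (0.0096; 4 and 3 adjusted over the list alone), led by Cxcl3 (1.37) and Cxcl5 (0.64). The genes of growth factor withdrawal fell in 8 of 15 cases and rose in 1 (5.7e-06), with Bcl6 at −0.53 and Foxo1 at 0.15. These calls held with an estimated correlation.

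Of the monocyte and macrophage attractants 6 of 15 rose in control cells and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.021, adjusted p = 0.0768 with an estimated correlation). Ccl9 (log2 0.89), Ccl2 (0.87 ± 0.114) and Il34 (0.52), a ligand of the CSF1 receptor, rose, and Vegfa fell (−0.23). Csf1 fell by 0.13 on the log2 scale (−0.13, adjusted p = 0.0035), and this call was lost without control replicate 3 and FCS-treated control replicate 4, left out after the data were seen (adjusted p = 0.0722). Other calls that did not hold were those of RAS-ERK targets (8 higher and 6 lower of 21, adjusted p = 0.0080 and 0.337 with an estimated correlation), extracellular matrix (9 higher and 6 lower of 24, 7.9e-05 and 0.0959 with an estimated correlation) and hypoxia (12 of 20 lower and 1 higher, 3.0e-05 and 0.0959 with an estimated correlation). Likewise lost were interferon response (5 of 22 lower, 0.031 and 0.156 with an estimated correlation), lung lineage (3 of 9 lower, 0.029 and 0.280 with an estimated correlation), macrophage markers (2 of 3 higher, 0.024 and 0.0768 with an estimated correlation) and fibroblast markers (3 of 4 lower, 0.0099 and 0.121 with an estimated correlation). For RAS-ERK targets the median was −0.00102, the mean 0.16 and the test up. Members were the phosphatase Dusp5 (0.53), Fosl1 (0.75), Spry1 (−0.44), Tnc (1.00), Col1a1 (−0.49), the mitophagy receptor Bnip3 (−0.76), Parp14 (−0.79) and the lung lineage factor Nkx2-1 (−0.57). The counts adjusted over the list alone were 8 and 7 for RAS-ERK targets, 1 higher and 4 lower for lung lineage and 4 lower for fibroblast markers, and were the same for the rest. The call of Cd68, a macrophage marker (0.30), was lost without control replicate 4 (adjusted p = 0.0513).

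Of 34 sphingolipid genes 9 rose and 5 fell in control cells, with the same counts adjusted over the list alone (list adjusted p = 0.605; median −0.00205, mean −0.04, test up), including Sgpp1, an S1P phosphatase (0.40), and Smpd2 (−0.31). S1pr2, Sphk2 (log2 −0.06), Kras (0.08, adjusted p = 0.081) and Trp53 (−0.07, adjusted p = 0.65) were not called. The remaining lists were not called (adjusted p from 0.0817 to 0.805), the immediate early genes among them, with 5 of 27 higher and 7 lower (5 and 10 adjusted over the list alone).

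In dSPHK1 cells FCS gave a wider response, and macrophage attractants rose. Ccl2 rose 10.3-fold, from 3.41 ± 0.321 to 35.1 ± 2.48 CPM (SD, n = 4; log2 3.36 ± 0.0924, SE; adjusted p = 2.3e-20, edgeR quasi-likelihood test). Il34 rose 4.65-fold, from 5.42 ± 0.551 to 25.3 ± 0.926 CPM, and Csf1 1.42-fold, from 73.5 ± 1.71 to 104 ± 1.37 CPM. Serpinb2 rose 16.2-fold, Cd109 9.98-fold, the hyaluronan synthase Has2 7.84-fold and Mmp13 7.61-fold. Of the genes tested 3181 rose and 3174 fell, 276 and 112 of them by at least 2-fold. With library totals 2715 rose and 3843 fell.

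Of the 15 attractants 11 rose and 1 fell (camera adjusted p = 8.7e-15), including Ccl7 (log2 3.18 ± 0.312), while Mif fell (−0.10), a call lost with no filter on low counts (adjusted p = 0.0913) and without dSPHK1 replicate 4 (0.104) or FCS-treated dSPHK1 replicate 1 (0.0997) or 4 (0.0628). The RAS-ERK feedback targets rose in 18 of 21 cases and fell in 2 (7.1e-25), with Dusp5 at 1.91, Fosl1 at 1.54 and Spry1 at −0.82. The immediate early genes rose in 20 of 27 cases and fell in 2 (4.5e-09), with Fosb at 1.46 and Btg2 at −0.67. NF-kB targets rose in 12 of 15 cases (7.8e-24), including Traf1 (1.63), Relb (1.33) and Nfkbia (1.18). Neutrophil attractants and inflammatory cytokines rose in 4 of 9 cases and fell in 3 (0.00039), with the prostaglandin synthase Ptgs2 rising from 89.2 ± 4.03 to 359 ± 14.3 CPM and Cxcl5 at 1.26. Unfolded protein response genes rose in 14 of 16 cases (3.4e-12), such as Creld2 (0.89) and Hyou1 (0.64), with Herpud1 lower (−0.19). Extracellular matrix genes were called up with 12 of 24 higher and 7 lower (1.7e-06; 12 and 8 adjusted over the list alone), with Tnc at 1.63 and Col1a2 at −1.29. Cholesterol synthesis fell in 18 of 23 cases and rose in 1 (1.3e-09), with Dhcr7 at −0.69 and the LDL receptor Ldlr at 0.17. Fatty acid synthesis fell in 11 of 13 cases (1.0e-11), with Fads2 at −0.78 and Scd2 at −0.75, and the genes of growth factor withdrawal in 10 of 15 cases with 2 higher (3.0e-07), with Pik3ip1 at −1.21, Sesn3 at −1.10 and Txnip at −0.95. These calls held with an estimated correlation, as did that of macrophage markers (3 of 3 higher, 0.00034), where Cd68 was 0.76, Cd14 0.64 and Mrc1 0.47. Only these 3 of the 15 markers had enough counts to test. In control cells without FCS they were present too, with Mrc1 at 105 CPM, Cd14 at 21.1 CPM and Cd68 at 6.24 CPM.

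Lists called in dSPHK1 cells with the preset correlation only were DNA replication (19 of 26 lower, 9.2e-05, adjusted p = 0.129 with an estimated correlation), fibroblast markers (4 of 4 lower, 0.0045, adjusted p = 0.0931 with an estimated correlation) and mitosis (14 of 25 lower and 1 higher, 0.0080, adjusted p = 0.247 with an estimated correlation). The others were ribosome biogenesis (13 of 20 higher and 1 lower, 0.0085, adjusted p = 0.280 with an estimated correlation), YAP/TAZ targets (10 of 21 higher and 3 lower, 0.013, adjusted p = 0.280 with an estimated correlation) and SRF targets (8 of 19 higher and 4 lower, 0.028, adjusted p = 0.247 with an estimated correlation). The median of the YAP/TAZ targets was 0.16, or 0.06 with the member at 0 counts set at its bound. The replication helicase genes Mcm5 and Mcm7 were both at −0.37, cyclin B2, Ccnb2, at −0.38, Itga5 at 1.31 and Crim1 at 0.72. Adjusted over the list alone, 20 replication genes and 15 mitosis genes were lower and 4 YAP/TAZ targets were lower, and the other counts of this comparison's called lists were the same except as given. Large decreases outside the lists were in Fmo2 (−1.99), the transcription factor gene Atoh8 (−1.76), the ketone synthesis enzyme Hmgcs2 (−1.46), Tox (−1.38), the transporter Abcc3 (−1.31) and the retinoic acid hydroxylase Cyp26b1 (−1.26). Of the sphingolipid genes 12 of 34 rose and 6 fell (12 and 7 adjusted over the list alone; list adjusted p = 0.158), including Plpp3 (0.94), and S1pr2 rose (0.36). Kras rose by 0.22, while Sphk2 (0.04, adjusted p = 0.54) and Trp53 (0.18, adjusted p = 0.11) were not called, and Trp53 was called without dSPHK1 replicate 1 (0.0414) or FCS-treated dSPHK1 replicate 2 (0.0328). The remaining lists were not called (adjusted p from 0.0928 to 0.886), and for lung lineage the median was −0.06, the mean 0.01 and the test down.

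**Figure D4:**
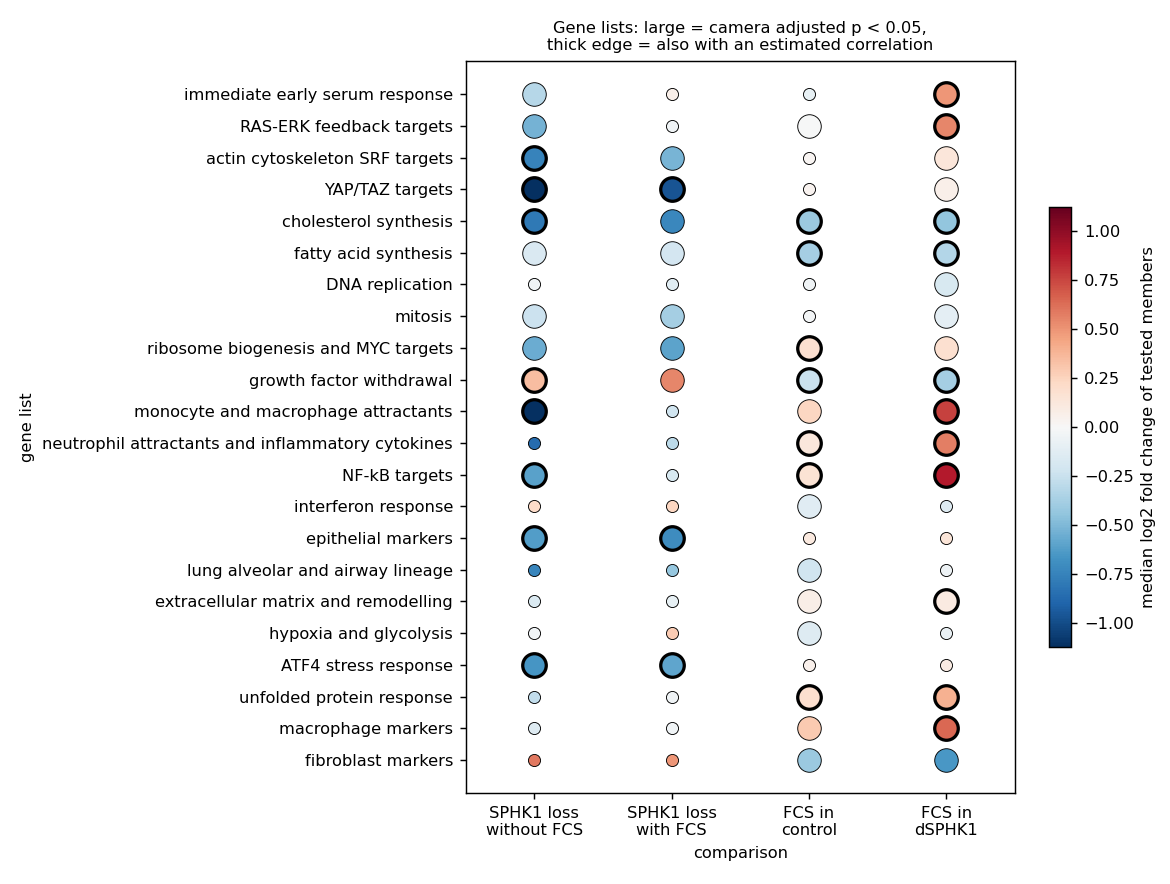
Median log2 fold change (colour) of the tested members of each gene list called at least once, for the 4 pairwise comparisons, with large circles where the camera adjusted p was under 0.05 and thick edges where the call held with an estimated correlation. The list of monocyte and macrophage attractants is low for SPHK1 loss without FCS (median −1.12) and high for FCS in dSPHK1 cells (0.77).

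The interaction asks whether the response to FCS differs between the genotypes. It did for macrophage attractants. The log2 effect of FCS on Ccl2 was 2.49 ± 0.157 (SE) higher in dSPHK1 than in control cells, a 5.61-fold difference (adjusted p = 4.8e-12, edgeR quasi-likelihood test). The difference was 1.72 ± 0.133 for Csf2, which encodes a growth factor of granulocytes and macrophages, 1.70 ± 0.085 for Il34 and 0.63 ± 0.0485 for Csf1. Il34 started lower in dSPHK1 cells and reached 25.3 ± 0.926 CPM (SD, n = 4) with FCS against 24.99 ± 0.815 CPM in control cells. Csf1 rose in dSPHK1 cells and stayed at 104 ± 1.37 CPM against 225 ± 9.68 CPM in control cells with FCS.

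In all, 1549 genes had a higher and 1004 a lower FCS effect in dSPHK1 cells, 88 and 33 of them by at least 2-fold. With library totals in place of TMM factors the higher share was 48.7% against 60.7%. Of these 2553 genes, 1244 had FCS effects of the same sign in both genotypes and larger in dSPHK1 cells, 163 had the same sign and smaller effects, and 1146 had effects of opposite sign, both called in 182. Of the genes FCS changed, 1481 rose in both genotypes and 1308 fell in both, where independent lists would share 483 and 479, and the FCS effects correlated with Pearson's r = 0.473 and Spearman's rho = 0.477 across genes. Has2 had 45.1 ± 1.56 CPM in control and 2.01 ± 0.296 CPM in dSPHK1 cells and rose in both, by 1.95 ± 0.105 more in dSPHK1 cells on the log2 scale, and Cd109 by 2.05 ± 0.154 more. The difference was negative for Atoh8 (−1.41 ± 0.075), Cyp26b1 (−1.33 ± 0.177) and Chst15 (−1.02 ± 0.1). It was −2.40 ± 0.699 for Tox, a call lost without FCS-treated control replicate 2 (adjusted p = 0.0768). Tox had 5 and 10 counts over the control groups. Smtnl2 passed by a small margin (−1.24 ± 0.439, adjusted p = 0.0483), and its call was lost when any 1 library was left out (0.0516 to 0.156) other than FCS-treated control replicates 2 and 4, dSPHK1 replicate 2 and FCS-treated dSPHK1 replicates 1 and 3.

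In 9 of 15 attractants the FCS effect was higher in dSPHK1 cells and in none lower (10 and none adjusted over the list alone; camera adjusted p = 2.2e-18). It was higher in 12 of 15 NF-kB targets (1.2e-25), 18 of 21 RAS-ERK targets with 1 lower (7.0e-34), 18 of 27 immediate early genes (1.9e-17) and 3 of 9 neutrophil attractants with 1 lower (0.0049). Adjusted over the list alone, 1 NF-kB target and 1 immediate early gene were also lower. These calls held with an estimated correlation. Without FCS these lists had negative medians in dSPHK1 against control cells: −1.12 (attractants), −0.61 (NF-kB), −0.53 (RAS-ERK), −0.32 (immediate early) and −0.87 (neutrophil attractants). With FCS the medians were −0.23, −0.18, −0.05, 0.07 and −0.30 in the same order. Their FCS effects thus started from lower medians, and none of these lists was called between the genotypes with FCS. The other lists, called with the preset correlation (adjusted p from 7.3e-05 to 0.0356), did not hold: SRF targets (6 of 19 higher and 1 lower, adjusted p = 0.188 with an estimated correlation), YAP/TAZ targets (10 of 21 higher and 1 lower, 0.249 with an estimated correlation), cholesterol synthesis (7 of 23 higher, 0.305 with an estimated correlation), unfolded protein response (10 of 16 higher and 1 lower, 0.172 with an estimated correlation), hypoxia (8 of 20 higher and 1 lower, 0.252 with an estimated correlation), extracellular matrix (8 of 24 higher and 2 lower, 0.353 with an estimated correlation), macrophage markers (2 of 3 higher, 0.0616 with an estimated correlation), DNA replication (9 of 26 lower, 0.197 with an estimated correlation), mitosis (6 of 25 lower, 0.262 with an estimated correlation) and growth factor withdrawal (5 of 15 lower and 2 higher, 0.262 with an estimated correlation). Adjusted over the list alone, 11 YAP/TAZ targets, 8 cholesterol genes, 12 unfolded protein response genes, 9 matrix genes and 3 macrophage markers were higher, 7 mitosis genes and 1 cholesterol gene were lower, and the other counts were the same. The sphingolipid genes (5 of 34 higher, adjusted p = 0.139) and the remaining lists were not called (0.116 to 0.976). The median, mean and test differed in sign for fatty acid synthesis, antigen presentation, mesenchymal markers and NRF2 targets, all uncalled. The FCS effects on Sphk1 (difference 0.00 ± 0.0812), Sphk2 (0.10, adjusted p = 0.34) and Trp53 (0.25, adjusted p = 0.21) gave no call. That on Kras differed by 0.14 (adjusted p = 0.035), a call lost with library totals (0.0716), with upper-quartile factors (0.0532) and when any 1 library was left out (0.0545 to 0.119) other than control replicate 3, FCS-treated control replicates 2 and 4, dSPHK1 replicate 3 and FCS-treated dSPHK1 replicates 1 and 4.

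**Figure D5:**
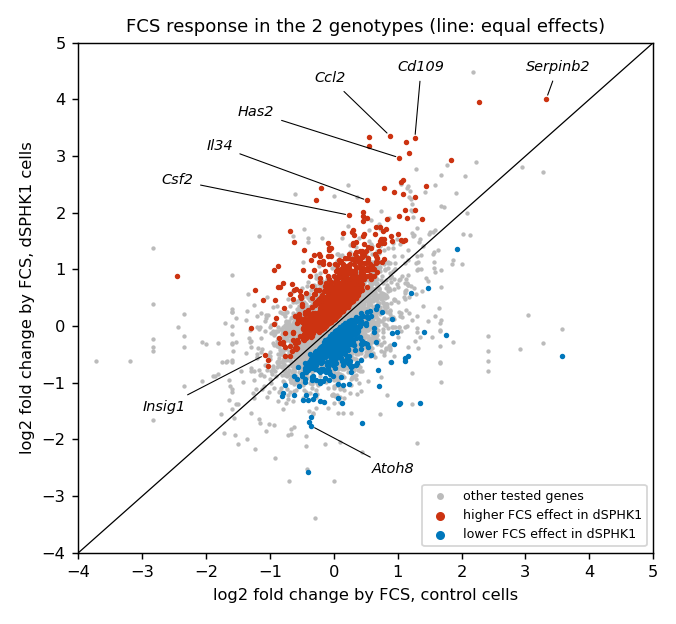
Log2 effect of FCS in control cells (x axis) and in dSPHK1 cells (y axis), 1 point per gene tested, with genes of a called interaction coloured and the line of equal effects drawn; 2 genes lie outside the plot. Ccl2, at 0.87 and 3.36, and Il34, at 0.52 and 2.22, lie above the line.

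RNA of other cell types was looked for with markers of macrophages, fibroblasts, endothelium and lymphocytes. Of 15 macrophage markers 3 reached 1 CPM in some group, namely Mrc1, Cd14 and Cd68, and the leukocyte gene Ptprc stayed at or under 0.0914 CPM on average in each group. Of 13 fibroblast markers 4 reached 1 CPM, among them the collagen genes Col1a1, at 79.6 CPM in control and 62.2 CPM in dSPHK1 cells, and Col3a1, at 9.24 and 178 CPM. The other 9 stayed at or under 0.359 CPM on average in each group. Among them, Pdgfra was at most 0.0584 CPM, Dcn at most 0.0497 CPM, and Thy1, Lum and Tcf21 were at 0 CPM. Of 11 endothelial markers 2 reached 1 CPM, and of 12 lymphocyte markers none did. Multimapping reads are not part of the gene counts, so genes with close copies are measured on the unique part of their sequence. The strand setting of the counting is not given in the sources used here, so a gene and an overlapping antisense gene may not be told apart.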

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

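The test of the spread between libraries and the count of neighbouring 2-fold genes were chosen after the results were seen. The split of the starting-level share by direction and the list medians beside it were not set beforehand either. The other tests here were. Of 140 groups of 4 values examined for a library far from the rest, 7 were marked, about the 1 in 20 that chance gives. The multimapping share was 10.6% in control replicate 3, below its group. The top 10 genes took 3.94% of the counts in FCS-treated dSPHK1 replicate 1. Il34 was 16.5 CPM in control replicate 2, Fosl1 174 CPM in FCS-treated control replicate 2 and Map2 49.6 CPM in FCS-treated dSPHK1 replicate 4. Mtap was 70.8 CPM in dSPHK1 replicate 1 and Cdkn2b 0.650 CPM in FCS-treated dSPHK1 replicate 2.

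The effect of FCS differed between the genotypes, by the interaction test, for 1549 genes upward and 1004 downward, 18.6% of those tested. It was called for 27 of the 34 genes compared here, a share largely set by their choice, since many were named for a large interaction or chosen after their values were seen. The FCS effect was higher in dSPHK1 cells for Ccl2 by 2.49 on the log2 scale, Csf2 by 1.72, Il34 by 1.70, Traf1 by 1.15, Csf1 by 0.63, Cxcl5 by 0.63 and Cd68 by 0.46. It was also higher for Cd109 (2.05), Has2 (1.95), Mmp13 (1.10), Serpinb2 (0.69) and Tnc (0.63). The ERK targets Dusp5 (1.39) and Fosl1 (0.79), Creld2 (0.36) and Kras (0.14) were higher as well. The secreted factors Inhba (1.28), Lif (1.28), Hbegf (0.95), Areg (0.77) and Ereg (0.75) were chosen after their values were seen. The difference was −0.38 for Spry1, −1.02 for Chst15, −1.24 for Smtnl2, −1.33 for Cyp26b1, −1.41 for Atoh8 and −2.40 for Tox. The call of Serpinb2 was lost with library totals (adjusted p = 0.0520), upper-quartile factors (0.0511), limma-voom (0.0862), without control replicate 3 and FCS-treated control replicate 4 (0.0515) and when any 1 library was left out (0.0560 to 0.150) other than control replicate 2, FCS-treated control replicates 1 and 4, dSPHK1 replicate 3 and FCS-treated dSPHK1 replicate 2. Those of Tox, Smtnl2 and Kras were lost as given with them above. By list, the adjusted p of the interaction with an estimated correlation was 8.6e-06 for NF-kB targets, 1.6e-05 for macrophage attractants, 0.00075 for RAS-ERK targets, 0.0066 for immediate early genes and 0.0388 for neutrophil attractants.

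The first pattern weighed is the extent of the difference between control and dSPHK1 cells. The values argue against a difference in sex between the lines. Xist, the RNA of the inactive X chromosome, was present in both genotypes, at 399 CPM in control and 697 CPM in dSPHK1 libraries. Y-linked RNA, summed over 4 genes, was 0 CPM in dSPHK1 libraries and 0.0055 CPM in control libraries, which alone would not settle it. Gained or lost genome segments may contribute: the medians of windows of neighbouring genes had an SD 2.58 times that of shuffled genes, which none of 1000 shuffles reached. For FCS in control cells the ratio was 1.23, which no shuffle reached either, so neighbouring genes also moved together to a smaller extent without a difference of genotype. Of the 2-fold genes 84.5% kept a 2-fold difference after the median of their window was subtracted, which had been set beforehand to count against segments as the whole cause. It does not decide this, because a median of 50 genes misses shorter segments. Cdkn2a (−4.83), Cdkn2b (−3.59) and Mtap (−2.92) are neighbours, and 529 of the 1716 genes that kept the difference lay next to another that kept it in the same direction, against at most 289 in 1000 shuffles. Genes regulated together would also lie side by side. What stays open is how much of the difference comes from segments, and whether the rest follows from the loss of SPHK1 or from a difference between the lines or clones that were grown, which the groups do not separate.

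The second pattern is the larger response to FCS in dSPHK1 cells. The median SD of log2 CPM was 0.066 and 0.076 in the dSPHK1 groups without and with FCS, against 0.082 and 0.084 in control cells. The groups shared 1 estimate of the spread per gene, so this would not by itself give more calls in dSPHK1 cells. It would not enlarge the effects either. With the compared samples alone, FCS gave 3611 calls in control and 6642 in dSPHK1 cells, against 4163 and 6355. The SD of FCS effects over 11659 genes, less the sampling part, was 1.48 times as large in dSPHK1 as in control cells (0.329 against 0.222, 95% interval of the ratio 1.41 to 1.56). The interval comes from resampling genes, which are not independent, with the libraries held fixed. It does not cover differences between libraries or cultures. TMM scaling is not the cause as a whole, since 91.0% of the interaction genes kept their call and sign with library totals. A different starting level without FCS could account for part of it: 49.4% (47.5% to 51.4%) of the interaction genes differed less between the genotypes with FCS than without, and this share decides neither way. Its interval counts genes as independent trials, which they are not. The share also pools 2 unlike parts. It was 53.5% (829 of 1549) for genes with a higher FCS effect in dSPHK1 cells and 43.1% (433 of 1004) for genes with a lower one. In the lists whose interaction call held with an estimated correlation, the median gap between the genotypes was smaller with FCS, as given above. This goes with a lower starting level for these lists and does not separate it from a stronger response. With these open, a stronger response to serum after SPHK1 loss is a hypothesis.

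Chance as the source of the calls was examined by relabelling libraries. For each pairwise comparison only the real split, 1 of 35, gave as many genes, and the highest of the other splits gave 0 genes for SPHK1 loss without FCS, with FCS and for FCS in dSPHK1 cells and 1 gene for FCS in control cells, against 10087, 10063, 6355 and 4163 real calls. The real split stood apart, and 1 of 35 is the smallest share possible. The other splits mix the groups, so the difference between the groups enters the spread and holds down the calls. Their low counts therefore do not measure how many genes chance would call. Chance differences between cultures or clones are not tested by the splits either. For the interaction only the real labels, 1 of 100 drawn, gave 2553 genes, and the highest other gave 0. This does not test the interaction, since relabelling FCS within a genotype also breaks the FCS effect that both genotypes share and adds it to the spread within groups.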

How the results depend on the processing

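The alternative that leaves out control replicate 3 and FCS-treated control replicate 4 together was chosen after the data were seen, and the others before. No named gene changed direction while called under the alternatives. The gene lists were rerun only with DESeq2 size factors, an estimated correlation and the replicate block, and none changed direction while called under these 3. In the pairwise comparisons the higher and lower counts were nearly even, so which was larger depends on the settings. With no filter it changed for SPHK1 loss with FCS (5515 higher and 5146 lower) and for FCS in control cells (1673 and 2027). The filter of 1 CPM changed it for FCS in control cells (2038 and 2152) and in dSPHK1 cells (3096 and 3125). It changed with limma-voom for FCS in dSPHK1 cells (3171 and 3196), and with the compared samples alone for SPHK1 loss without FCS (4971 and 4916). DESeq2, the block and some libraries left out also changed it in some comparisons. The larger side changed with the scaling too. It changed for SPHK1 loss without FCS and for FCS in dSPHK1 cells with DESeq2 size factors (5088 higher and 4976 lower, 3123 and 3225) and upper-quartile factors (5135 and 4926, 2872 and 3608), for SPHK1 loss with FCS with DESeq2 size factors (5076 and 4978) and for FCS in control cells with upper-quartile factors (1981 and 2230). With library totals it changed in each of the 5 comparisons, with 6084 and 4011 for SPHK1 loss without FCS, 5800 and 4216 with FCS, 1983 and 2193 for FCS in control cells, 2715 and 3843 for FCS in dSPHK1 cells, and 1318 and 1388 for the interaction. Requiring a log2 fold change of at least 1 lowered the counts by construction, to 1275 higher and 758 lower for SPHK1 loss without FCS, 1311 and 688 with FCS, 99 and 48 for FCS in control cells, 276 and 112 for FCS in dSPHK1 cells, and 88 and 33 for the interaction. Sphk1 in control cells with FCS moved from 22.3 to 21.5 CPM with library totals, which replace the scaling. No other setting moved a count by over 1.5 times, and the interaction had the fewest lower genes, 679, with no filter. With 1 library left out the counts ranged from 4808 to 4888 higher and 4977 to 5068 lower for SPHK1 loss without FCS, 4815 to 4951 and 4878 to 5042 with FCS, 1729 to 2049 and 1712 to 2035 for FCS in control cells, 2899 to 3077 and 2863 to 3030 for FCS in dSPHK1 cells, and 1295 to 1596 and 818 to 1048 for the interaction. Without the pair left out together, FCS in control cells kept 71.0% of its calls and the interaction 76.7%. Calls of FCS in control cells, new ones included, were then 1604 higher and 1535 lower.

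Of 234 named gene values, 47 of 2112 lost their call and 4 gained one with 1 library left out, and 11 of 2310 lost and 1 gained one under the other settings, apart from the fold threshold, where 95 were lost, and the block. Under the 3 settings tried for lists, calls were lost with an estimated correlation, as given with each list, and under the block. Lists were not rerun with other scalings or filters, other tests or libraries left out, and the cause of the losses was not tested.

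The sources do not say whether the replicate numbers pair the libraries. The correlations of same-numbered deviations ran from −0.0745 to 0.0724, none of 16 over 0.1. In 8 of the 16 the best match had the same number, where about 4 are expected by chance, so a weak pairing is not excluded. With the replicate number as a block, FCS in control cells gave 2380 higher and 2370 lower genes, and the interaction 1884 and 1381. Under the block Kras was called for FCS in control cells (adjusted p = 0.0344) and the interferon list was not (0.0554). Depth limits genes of a few counts per group, such as Tox in control cells.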

Other observations

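The genes described here were chosen after their values were seen. A set of neighbouring tumour suppressor and metabolic genes on chromosome 4 was low in dSPHK1 cells. Cdkn2a, which encodes the inhibitors p16 and p19ARF, was 144 ± 6.49 CPM (SD, n = 4) in control and 5.11 ± 1.09 CPM in dSPHK1 cells (log2 −4.83 ± 0.0702, SE). Its neighbour Cdkn2b was 14.1 ± 0.973 and 1.16 ± 0.165 CPM (−3.59 ± 0.105), and Mtap, a methionine salvage enzyme, 549 ± 20.02 and 72.7 ± 1.26 CPM (−2.92 ± 0.0359). Klhl9, next to them, was not called (−0.08, adjusted p = 0.089, edgeR quasi-likelihood test), and was called with no filter on low counts (0.0364), without control replicate 1 (0.0351) and without dSPHK1 replicate 3 (0.0453). With FCS the values were similar, −4.92 for Cdkn2a and −2.77 for Mtap.

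Several secreted growth factors rose more with FCS in dSPHK1 than in control cells. Lif, a cytokine of the interleukin 6 family, was lower in dSPHK1 cells without FCS (log2 −1.19), rose with FCS in these cells (1.24) and did not pass in control cells (−0.04). Inhba, a subunit of activin, rose by 1.60 in dSPHK1 and 0.32 in control cells, and the EGF receptor ligand genes Ereg (1.54 and 0.78) and Hbegf (1.10 and 0.15) rose in both, as did Areg (2.82-fold and 1.65-fold). Cd274, which encodes the immune checkpoint ligand PD-L1, was higher in dSPHK1 cells without FCS (2.17 ± 0.0722) and with FCS (2.63). Xist, the RNA of the inactive X chromosome, was 399 CPM in control and 697 CPM in dSPHK1 libraries.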
